A study of Mus musculus with 15 samples.

How the data were processed

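Macrophages positive for F4/80 and CD45 were sorted from C57BL/6J mice and profiled directly after isolation by low-input RNA-seq of total RNA, per the labels. The 15 libraries fall into 6 groups by tissue: sympathetic ganglia (SAM ganglia, 3 libraries), sympathetic nerve fibers taken from inguinal fat (SAM fibers, 2), subcutaneous fat (sATM, 2), visceral fat (vATM, 2), spleen (SpM, 3) and brain (microglia, 3). Here SAM stands for the macrophages of the ganglia and fibers together, and a library is named by its group and the replicate number in its title. Tissues came from 10 mice, per the labels, which do not say whether libraries of a group came from separate animals. The p-values therefore measure the spread between libraries, which may be technical.

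Digestion differed between tissues, per the labels' protocols. Fat, spleen and brain were held in collagenase for 30 minutes. Fibers had hyaluronidase for 30 minutes and then collagenase for 15 minutes, and ganglia had collagenase for 10 minutes and then trypsin for 30 minutes. All steps were at 37 °C.

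STAR, HOMER and the mouse genome build mm10 are named in the submitters' processing notes. Their versions and settings, the sequencing layout and whether counting used strand are not given in the sources used here. Tables of the whole series were used, 3 in number. The main table holds estimated counts per gene from which the authors removed reads of DNA contamination before it was deposited (24084 genes). In it 45.3% of the values were whole to within 1e-09, with whole values in every library for all single-exon genes and 13.2% of multi-exon genes. The second table holds raw counts over whole gene bodies, introns included, as the authors deposited them without that removal (24525 genes); its gene length equalled the genomic span for 99.4% of genes. The third holds RPKM values, reads per kilobase of gene and M mapped reads, as the authors deposited them (24414 genes), scaled to between 1.005 and 1.009 times the table's own total. Symbols turned into dates by a spreadsheet were resolved by their transcript identifiers for all 25 such genes.

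The corrected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 15289. Libraries were scaled by TMM (factors 0.668 to 1.40), and a model with 1 mean per group was fitted over all 15 libraries, which share 1 estimate of the spread because 3 groups have only 2 libraries. The common biological coefficient of variation was 0.680. Each comparison was a quasi-likelihood F-test with Benjamini-Hochberg adjustment over the 15289 genes. A gene was called higher or lower at an adjusted p below 0.05 with a log2 fold change of at least 1 in size. Rose and fell are used only of called genes and lists. The comparisons were SAM against the other macrophages (the mean of both SAM groups minus the mean of the other 4, each group weighted equally on the log scale), fibers against sATM, ganglia against fibers, ganglia against microglia, and sATM against vATM. Levels are mean counts per M counts (CPM) after TMM scaling ± SD, with n = 3 for ganglia, spleen and microglia and n = 2 for fibers, sATM and vATM. Fold changes are log2 values ± SE of the fit.

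Before the data were examined, 33 gene lists, the comparisons, the tests and most alternatives were fixed. A list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the 32 lists that had at least 3 tested genes. Its members were counted by the rule for single genes, and again adjusted over the list alone. The lists hold textbook markers, and some genes stand in more than 1 list. The genes named were fixed by rule. They are, for each comparison, the 10 called genes with the largest fold change in each direction that have a mean of at least 30 CPM on the higher side and no overlap between libraries of the sides compared, leaving out predicted, clone-named, small RNA, mitochondrial and receptor-segment genes. To these were added the tested genes of norepinephrine uptake and breakdown, Adgre1 and Ptprc (which encode F4/80 and CD45), and up to 4 members of each other list, called members with the smallest p first. Some genes that this rule names are not reported here. Levels given for a named gene in groups outside a comparison were read afterwards.

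A value of 0 in the corrected table can be a failed estimate, since genes with large raw counts are listed at 0 there. For a gene listed at 0 in all libraries of a side no fold change is given, and its raw gene-body counts are printed. The lowest level distinguishable from 0 was taken as 3 counts in a library, or 0.249 to 0.897 CPM, which covers counting error only. A list's median at the bound sets genes listed at 0 on a side to 3 counts over all libraries of that side. Background DNA was measured as raw gene-body counts of 1125 olfactory receptor genes per M raw counts (M for mega). Near-identical copies (Hspa1a and Hspa1b, Hba-a1 and Hba-a2, Ear2 and Ear12) may share reads and are uncertain, as are overlapping and antisense genes.

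Alternatives, whose effects are given in the closing section, were the raw gene-body table, DESeq2 1.42.0, RLE factors, no or stricter filters, limma on log2(RPKM + 1) and log2(RPKM + 0.1), voom with quality weights, fits of only the groups compared, replicate numbers as a block, no minimum fold change, other reference groups and weights, and leaving out each library in turn. Added after the data were seen were a fit without the ribosomal RNA-type genes, DNA background as a covariate, leaving out the library with most DNA background in each group, and genes called in both count tables. The pipeline was tested on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold. The share recovered at 4-fold was 94% for SAM against the others, 41% for fibers against sATM, 48% for ganglia against fibers, 65% for ganglia against microglia and 37% for sATM against vATM. At 16-fold it was 92% to 100%. Genes of low mean level were not among those changed, and the simulated counts held no DNA background and no failed estimates. The shares therefore do not apply to low genes such as Slc6a2 and Slc22a3 or to genes wrongly listed at 0. No libraries of a group agreed within counting noise (chi-square per degree of freedom 11.99 to 70.7), so none was counted as a duplicate. Groups of 2 or 3 libraries were taken as too small to judge whether a library lies far from its group. No column of the tables was left unmapped. Tables were handled with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Reads were not used here.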

Results

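Gene expression was measured in F4/80- and CD45-positive macrophages sorted from 6 tissue sources in mice, in 15 libraries. The sources were sympathetic ganglia (n = 3) and nerve fibers (n = 2), whose cells are called SAM here, subcutaneous fat (sATM, n = 2), visceral fat (vATM, n = 2), spleen (SpM, n = 3) and brain (microglia, n = 3). The series title points to uptake and breakdown of norepinephrine, the transmitter of sympathetic neurons, by macrophages that sit on those neurons. The corrected table held 2.55 to 12.52 M counts per library (M for mega, median 5.93 M). Rn45s, Lars2 and Mir6236, which collect ribosomal RNA reads, took 46.1% to 71.5% of them, and the other genes had 1.20 M (SAM fibers 1) to 4.82 M counts (SpM 1). Between 12707 and 17388 genes were detected per library. DNA background, as olfactory receptor gene-body counts per M raw counts, averaged 959 in fibers, 556 in microglia, 351 in ganglia, 288 in spleen, 207 in sATM and 155 in vATM. It was highest in SAM fibers 1 (1233), Microglia 2 (1085), SAM ganglia 3 (857) and SAM fibers 2 (686). Some genes with at least 100 raw counts were listed at 0 after the authors' correction. They were 40.8% of 17284 such genes in SAM fibers 1 and 22.5% of 13690 in SAM fibers 2, against 4.28% of 8522 in vATM 1. Raw counts include DNA reads, so a 0 need not be a failed estimate. The correction did not remove all DNA background. Between 13.8% (SpM 1) and 62.8% (Microglia 2) of the raw olfactory receptor counts remained after it. The share was 57.9% in SAM fibers 1 and 58.4% in SAM fibers 2. Part of the drop may be introns left out, since gene length in the corrected table equalled the genomic span for only 6.47% of genes. Single-exon genes kept whole values there and most multi-exon genes did not. The shares therefore do not measure the DNA left in multi-exon genes.

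**Figure D1:**
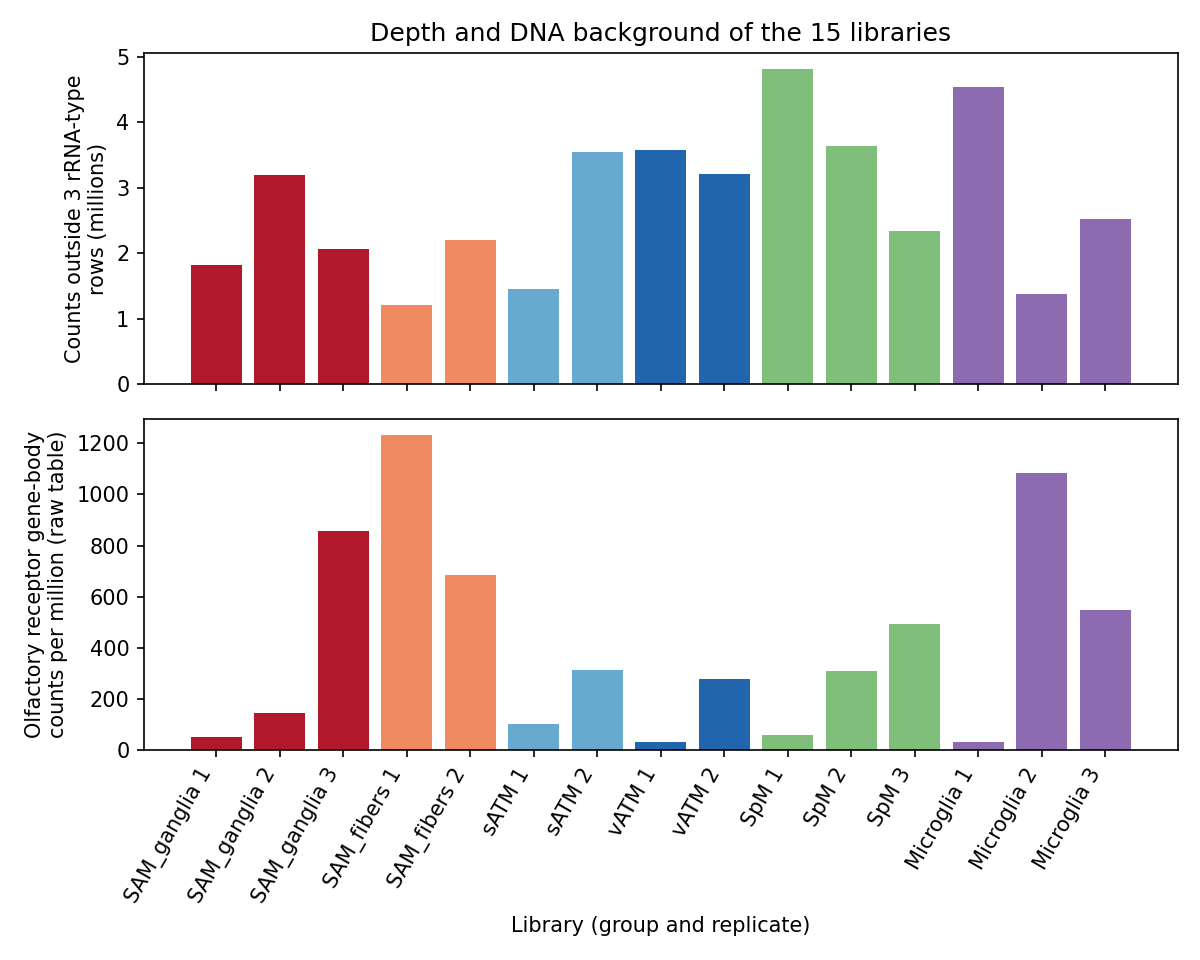
Bars give, for each of the 15 libraries, the corrected counts outside 3 ribosomal RNA-type genes in M (top) and olfactory receptor gene-body counts per M raw counts (bottom). SAM fibers 1 has the fewest counts (1.20 M) and the highest background (1233).

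The sorted cells carried the markers of their tissues. In microglia against the mean of the other groups, 16 of 17 microglial genes were higher (median log2 difference 5.69, adjusted p = 2.57e-09 with an estimated correlation), among them the purinergic receptor P2ry12 (6.62 ± 0.21), Tmem119 (8.24 ± 0.31) and Sparc (6.57 ± 0.20). In spleen, 14 of 15 genes of red pulp macrophages, which recycle iron from aged red cells, were higher (median 6.56, adjusted p = 3.33e-08), including the iron exporter Slc40a1 (7.14 ± 0.20), the transcription factor Spic (6.99 ± 0.39) and Vcam1 (7.52 ± 0.35). In the fat groups, 12 of 17 genes of resident adipose and perivascular macrophages were higher (median 2.82, adjusted p = 4.29e-04), among them Retnla (8.99 ± 0.57), F13a1 (4.48 ± 0.31) and the lectin Cd209f (8.21 ± 0.58). Several of these genes were near 0 in spleen and microglia, and not every member was higher in fat than in ganglia. Mrc1 averaged 1173 CPM in ganglia against 429 in sATM and 790 in vATM, and Stab1 468 against 45.7 and 202. By camera the list did not pass between fibers and sATM (adjusted p = 0.725). The transcripts of the sort markers were present in every group. Adgre1 ranged from 161 ± 45.2 CPM in sATM to 538 ± 79.4 in spleen, and Ptprc from 174 ± 43.6 in microglia to 769.6 ± 91.9 in spleen. Neither passed the test between SAM and the other macrophages (Adgre1 0.25 ± 0.17, adjusted p = 0.325; Ptprc -0.67 ± 0.23, adjusted p = 0.0684), though Ptprc was lower in SAM without microglia in the reference (-1.10, adjusted p = 0.00747). The 2 fiber libraries correlated at 0.605 on log2 CPM (Pearson), against 0.781 to 0.959 for other pairs of a group. SAM fibers 2 correlated more with the ganglia libraries (0.767 to 0.787), and as much with sATM (0.767 and 0.783) and vATM (0.770 and 0.780). Fiber means thus join 2 unlike libraries. In a principal component analysis of all tested genes, component 1 (32.1% of variance) set SAM fibers 1, the library with most DNA background, far from the rest at 272. Components 2 (18.8%) and 3 (14.1%) separated brain and spleen from the other groups.

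**Figure D2:**
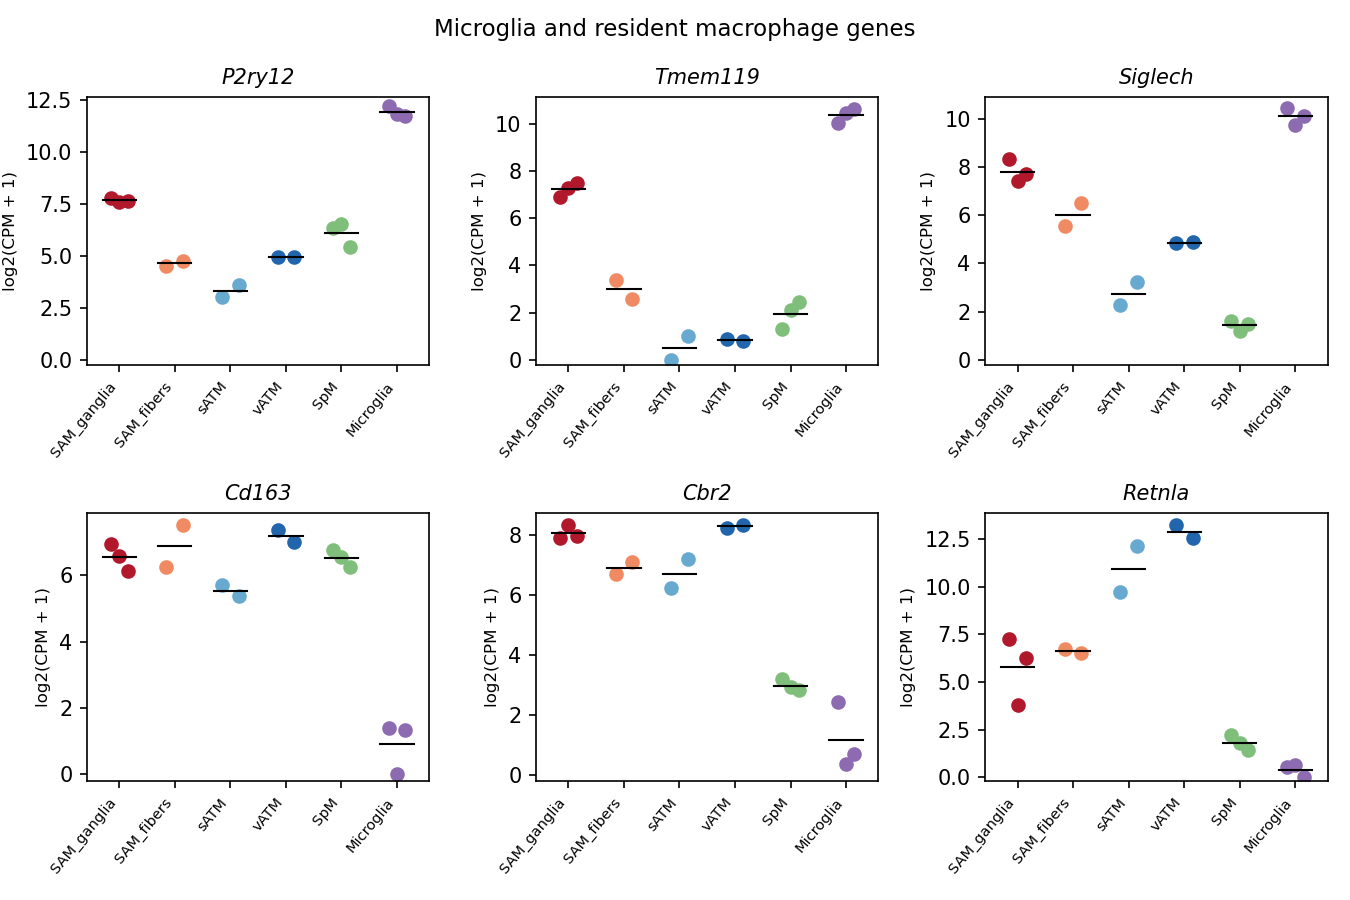
Points are libraries and black lines group means of log2(CPM + 1) for 3 microglial markers (P2ry12, Tmem119, Siglech) and 3 genes of resident adipose and perivascular macrophages (Cd163, Cbr2, Retnla) in the 6 groups. Retnla averaged 7874 CPM in vATM and 0.331 CPM in microglia.

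**Figure D3:**
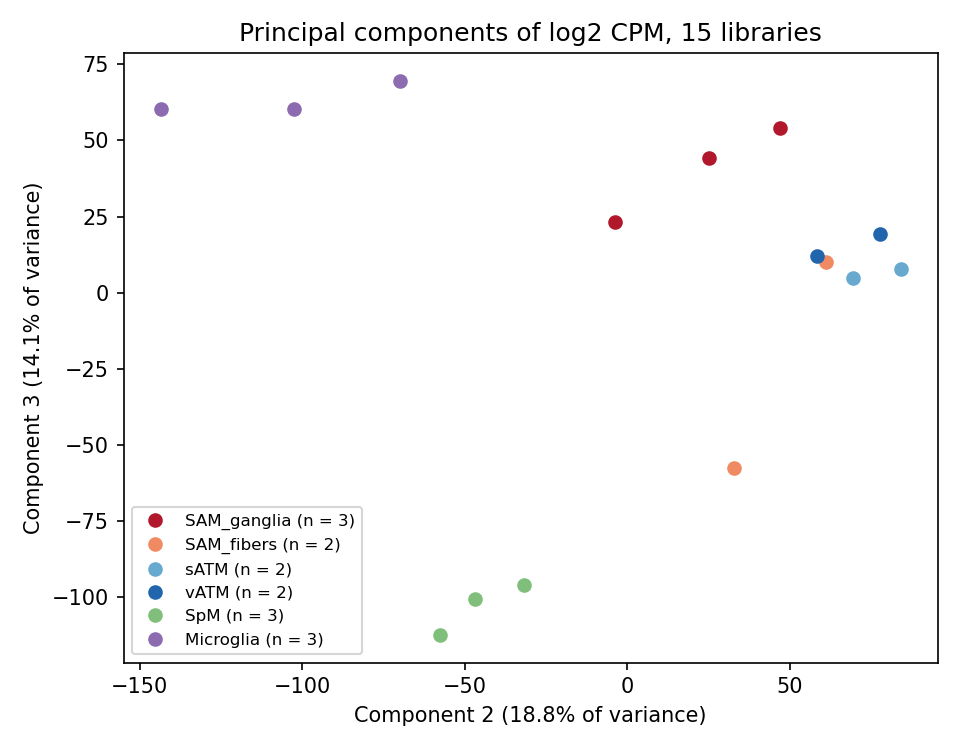
Each point is a library, coloured by group, on components 2 (18.8% of variance) and 3 (14.1%) of log2 CPM. Microglia lie at the low end of component 2 and spleen at the low end of component 3.

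The broadest comparison asked what set SAM apart from the macrophages of fat, spleen and brain. Immediate-early and heat-shock genes, which many cells switch on within minutes of stimulation or stress, rose throughout. All 18 genes of that list were higher in SAM (18 adjusted over the list alone, median log2 fold change 3.76). The AP-1 gene Fosb (chromosome 7, 19302696 to 19310045) averaged 1311 ± 363 CPM in fibers, 171 ± 21.9 in ganglia, 123 ± 1.60 in sATM and 119.8 ± 14.6 in vATM, against 0.330 ± 0.328 in spleen and 0.210 ± 0.230 in microglia (6.28 ± 0.28, adjusted p = 1.67e-09). Fos (5.43 ± 0.39), Atf3 (4.55 ± 0.18), Egr1 (5.38 ± 0.24) and the heat-shock gene Hspa1a (4.82 ± 0.22) rose too. The levels in fat thus lay closer to those of ganglia than to those of spleen or brain. Spleen and microglia lie near or under the floor for Fosb, and groups near 0 pull down the reference, since the comparison averages log levels. Pro-inflammatory genes rose as well, 15 of 19 being higher (15 adjusted over the list alone, median 3.31). They included the chemokines Ccl4 (5.003 ± 0.24; 1246 ± 88.6 CPM in fibers, 378 ± 98.9 in ganglia and 99.7 ± 26.8 in sATM) and Ccl3 (4.85 ± 0.23), the cytokine Il1b (4.55 ± 0.29) and the NF-κB regulator Nfkbiz (3.42 ± 0.25). Of the anti-inflammatory list, 6 of 16 genes were higher (7 adjusted over the list alone, median 1.48). Among them were the cytokine signalling inhibitor Socs3 (3.79 ± 0.24), the transcription factor Klf4 (3.14 ± 0.21), the lectin Mgl2 (4.60 ± 0.56) and the scavenger receptor Cd163 (1.91 ± 0.29). The chemokines Ccl7 (5.67 ± 0.50) and Ccl12 (5.65 ± 0.36) were among the 10 largest increases. These 3 lists passed camera's test (adjusted p = 1.25e-134, 1.72e-39 and 1.24e-07; with an estimated correlation 3.65e-05, 0.00303 and 0.0243).

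**Figure D4:**
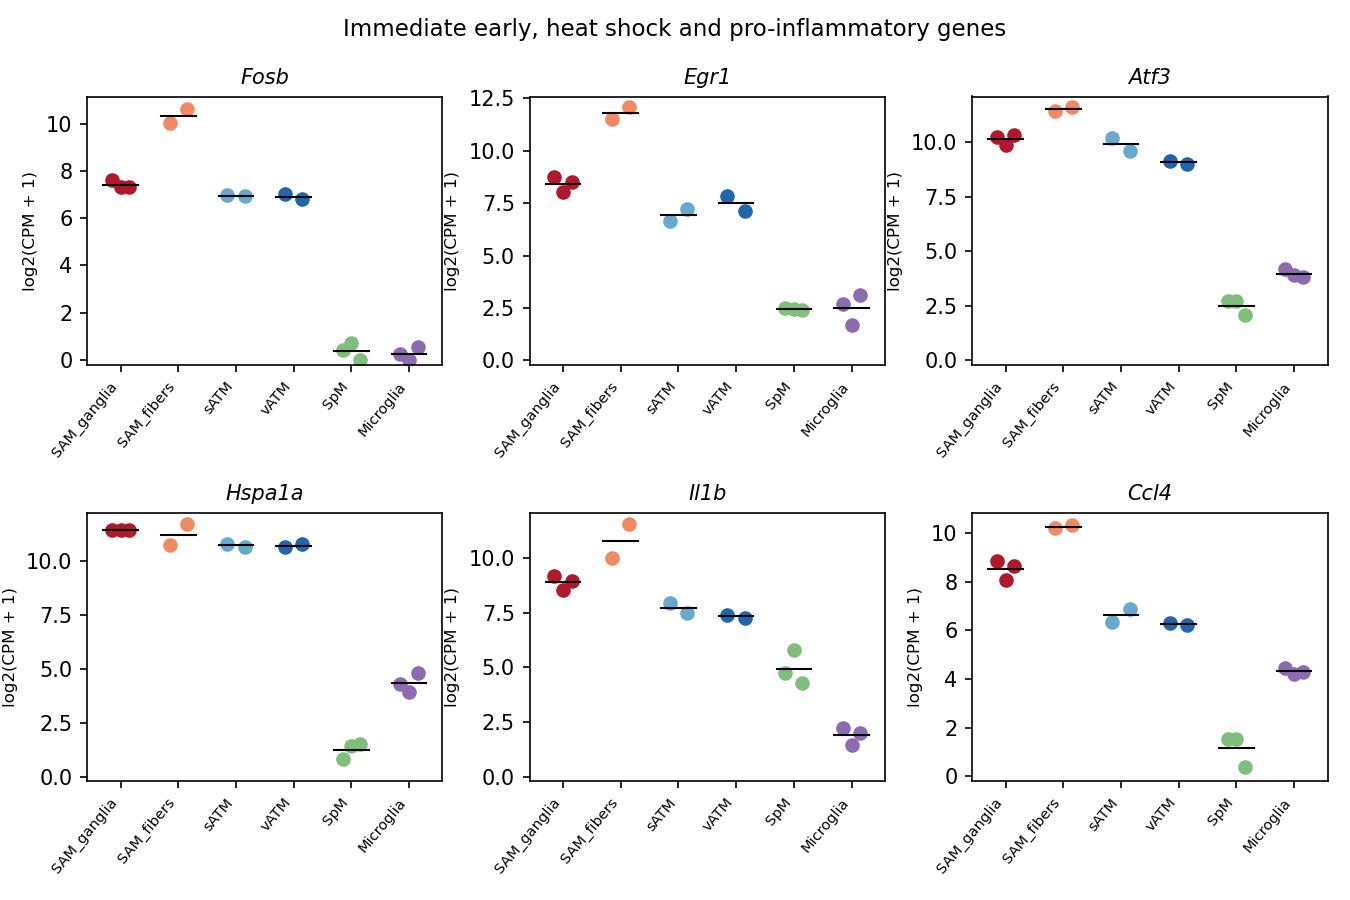
Points are libraries and black lines group means of log2(CPM + 1) for 4 immediate-early or heat-shock genes (Fosb, Egr1, Atf3, Hspa1a) and 2 inflammatory genes (Il1b, Ccl4). Fosb averaged 1311 CPM in fibers and 0.210 CPM in microglia, with ganglia and both fat groups in between.

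Transcripts of neurons and of other cells moved with the SAM libraries. Of the sympathetic neuron list, 19 of 20 genes were higher in SAM (19 adjusted over the list alone, median 4.08, adjusted p = 1.43e-29, 0.00142 with an estimated correlation). The neuropeptide Npy averaged 134 ± 78.3 CPM in fibers, 26.6 ± 5.58 in ganglia and 8.75 ± 3.11 in sATM (4.64 ± 0.28). Uchl1 (5.02 ± 0.40), Stmn2 (4.11 ± 0.36) and Pcsk1n (5.45 ± 0.49), all abundant in neurons, showed the same order. Catecholamine synthesis genes rose (5 of 8, and 5 adjusted over the list alone; median 2.76, adjusted p = 1.26e-04, 0.0153 with an estimated correlation). They included Dbh, which makes norepinephrine from dopamine (chromosome 2, 27165507 to 27183204; 4.94 ± 0.59), and Th, the rate-limiting enzyme (chromosome 7, 142892776 to 142899966; 4.72 ± 0.67), with Cyb561 (4.39 ± 0.71) and Gch1 (1.86 ± 0.29). Schwann cell and satellite glia genes rose (9 of 16, and 13 higher with 1 lower adjusted over the list alone; median 2.82, adjusted p = 4.45e-10, 0.00719 with an estimated correlation). Apod (chromosome 16, 31296192 to 31314808; 5.71 ± 0.53), the myelin gene Pmp22 (2.05 ± 0.26) and the adhesion gene Ncam1 (3.25 ± 0.50) were in this list. Fibroblast genes rose (8 of 12, and 8 higher with 1 lower adjusted over the list alone; median 3.30, adjusted p = 1.47e-11, 0.00111 with an estimated correlation). The collagen gene Col1a1 (0 in all spleen libraries) and Dcn (4.08 ± 0.48) were among them. Hemoglobin and other erythroid genes rose (5 of 8, and 5 higher with 1 lower adjusted over the list alone; median 2.81, adjusted p = 2.58e-08, 0.0372 with an estimated correlation), including Hbb-bs (3.24 ± 0.31). For central glia 3 of 9 genes were higher (5 adjusted over the list alone, median 2.71, adjusted p = 0.00704). The call was lost with an estimated correlation (adjusted p = 0.147).

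Among genes that take up or break down norepinephrine, 3 of 8 tested were higher in SAM (3 adjusted over the list alone), while the list as a whole did not pass (median 1.54, adjusted p = 0.0696, and 0.137 with an estimated correlation). Maoa, the mitochondrial enzyme that degrades norepinephrine (chromosome X, 16619698 to 16687812), averaged 16.9 ± 4.80 CPM in fibers, 14.4 ± 5.95 in ganglia, 7.83 ± 0.917 in vATM, 2.36 ± 3.33 in sATM, 1.64 ± 0.334 in microglia and 0.129 ± 0.157 in spleen (3.44 ± 0.56, adjusted p = 7.72e-04). Slc6a2, the norepinephrine transporter (chromosome 8, 92961047 to 93001667), averaged 13.1 ± 11.5 CPM in fibers, 5.55 ± 5.04 in ganglia, 1.40 ± 1.98 in sATM, 0.841 ± 0.798 in spleen, 0.787 ± 0.692 in microglia and 0.243 ± 0.00448 in vATM (3.59 ± 0.89, adjusted p = 0.0156). Its counts were 71 and 24 in fibers, 49, 25 and 10 in ganglia, 11 and 0 in sATM, 2 and 2 in vATM, 1, 7 and 11 in spleen, and 15, 0 and 7 in microglia. For Maoa they were 68 and 65, 63, 153 and 42, 0 and 41, 60 and 69, 1, 0 and 2, and 15, 7 and 11 in the same order. Slc22a3, a low-affinity monoamine transporter (chromosome 17, 12419974 to 12507704), had 23 and 0 counts in fibers, 0, 12 and 10 in ganglia, 0, 3 and 5 in microglia, 0 and 2 in sATM and 0 in all vATM and spleen libraries (adjusted p = 0.0477). With 2 reference groups at 0 no fold change is given. The vesicular transporter Slc18a2 (-0.31 ± 0.70, adjusted p = 0.792), Slc29a4 (0 in both vATM libraries, adjusted p = 0.143), Aldh2 (0.44 ± 0.32, adjusted p = 0.36) and Akr1a1 (-0.19 ± 0.16, adjusted p = 0.425) were not called. Maob and Slc22a2 were too low to test. The Slc6a2 call was lost without SAM fibers 1 (adjusted p = 0.0922), SAM ganglia 1 (0.0553), vATM 1 (0.0727) or vATM 2 (0.0697). That of Slc22a3 was lost in 23 of 31 alternatives, 12 of them single libraries left out (without SAM fibers 1, adjusted p = 1). The raw gene-body table called neither Maoa (adjusted p = 0.423) nor Slc6a2 (0.504). Adrenergic receptor genes had 1 of 6 higher (1 adjusted over the list alone). The list's call (median 1.33, adjusted p = 0.0449) was lost with an estimated correlation (adjusted p = 0.242).

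**Figure D5:**
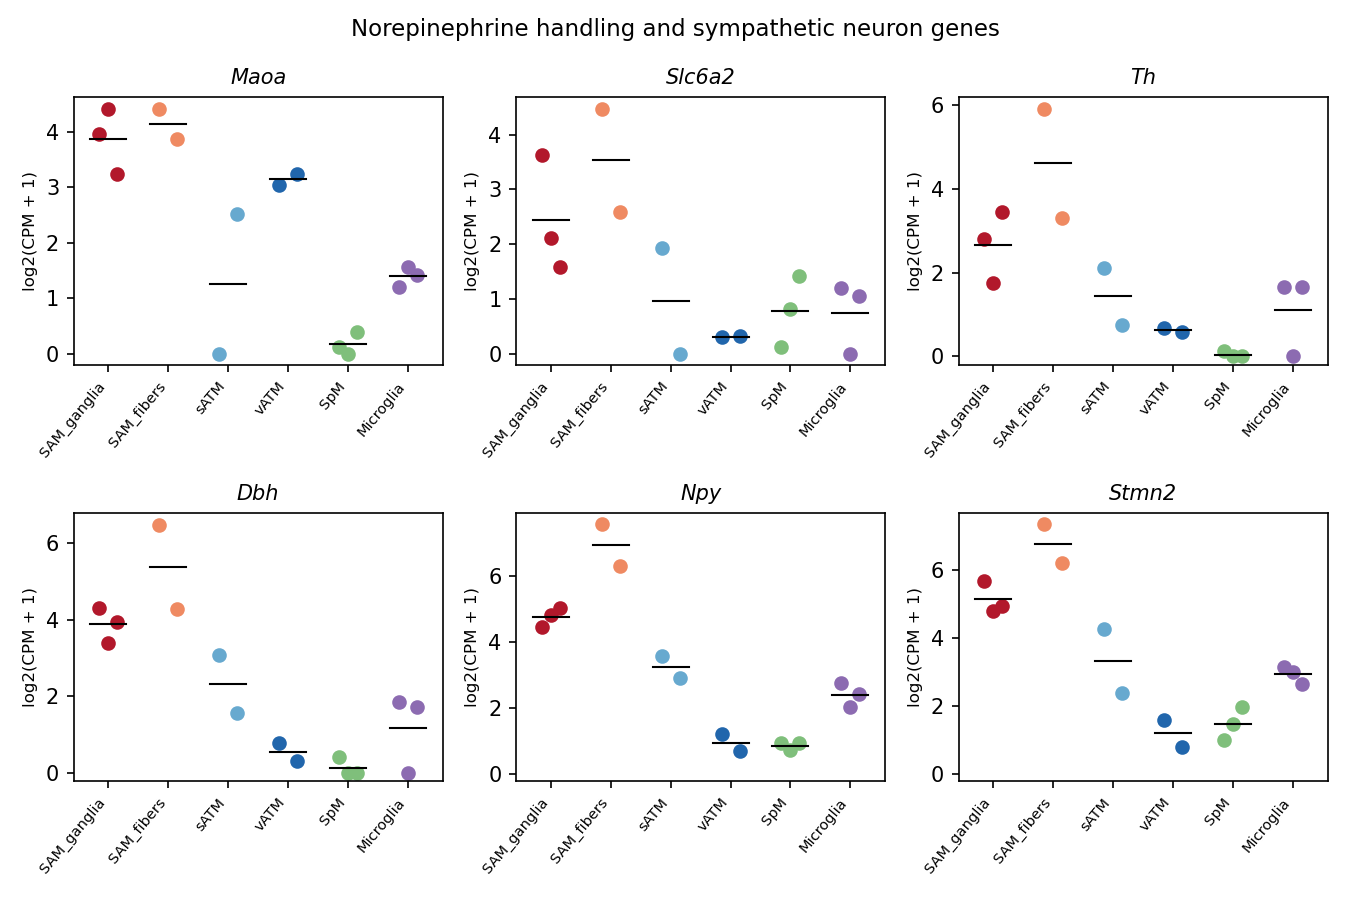
Points are libraries and black lines group means of log2(CPM + 1) for Maoa, Slc6a2 and 4 genes abundant in sympathetic neurons (Th, Dbh, Npy, Stmn2). Slc6a2 averaged 13.1 CPM in fibers and 5.55 CPM in ganglia, where Dbh averaged 52.9 and 14.2 CPM.

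Macrophage identity genes also differed between SAM and the rest. The microglia list rose (9 of 17, and 9 adjusted over the list alone; median 2.03, adjusted p = 2.40e-12, 4.07e-04 with an estimated correlation). Olfml3 (3.96 ± 0.36), Trem2 (2.75 ± 0.28) and Siglech (2.36 ± 0.23) were higher on the log scale. Microglia themselves had more Siglech, 1125 ± 279 CPM against 232 ± 77.3 in ganglia. Resident adipose and perivascular genes rose (11 of 17, and 11 adjusted over the list alone; median 1.59, adjusted p = 2.68e-12, 0.0153 with an estimated correlation). An example is Stab1 (3.15 ± 0.29). Pf4 (3.91 ± 0.34) and F13a1 (3.10 ± 0.31) rose on the log scale, on which the low levels of spleen and microglia weigh most. F13a1 was higher in fat, with 841 CPM in vATM and 570.3 in sATM against 459 in ganglia and 293 in fibers, and Pf4 was highest in vATM (302 CPM, 285 in fibers). MHC class II genes, which present antigen, had 6 of 10 higher and 1 lower (the same counts adjusted over the list alone; median 1.35, adjusted p = 8.61e-07, 0.0329 with an estimated correlation). H2-Eb1 (2.51 ± 0.32) and Cd74 (2.12 ± 0.32) were higher. A further 4 lists passed only with the preset correlation. Interferon response genes had 5 of 15 higher (9 adjusted over the list alone; median 1.18, adjusted p = 7.40e-06, and 0.0958 with an estimated correlation). Complement and phagocytic receptors had 4 of 19 higher (6 higher and 2 lower adjusted over the list alone; median 0.18, adjusted p = 0.00291, and 0.163 with an estimated correlation). Neurotrophic and growth factors had 1 of 12 higher, the cytokine Osm (3.20 ± 0.29; 1 adjusted over the list alone; median 1.73, adjusted p = 0.00612, and 0.0573 with an estimated correlation). Monocyte genes had 5 of 10 higher (7 higher and 1 lower adjusted over the list alone; median 1.61, adjusted p = 3.19e-05, and 0.093 with an estimated correlation).

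The remaining lists did not pass between SAM and the other macrophages. Red pulp genes had 3 of 15 lower (adjusted over the list alone 3 lower and 1 higher; median -0.04, adjusted p = 0.179), Slc40a1 (-2.52 ± 0.22), Fcna (-4.76 ± 0.53) and Cd5l (-3.08 ± 0.77), all abundant in spleen. Lipid handling genes went both ways (3 of 14 higher and 1 lower, and 4 and 3 adjusted over the list alone; median -0.11 but mean 0.10, adjusted p = 0.193). Apoe (2.44 ± 0.21) and Cd36 (2.85 ± 0.23) were higher and the cholesterol exporter Abcg1 (-2.45 ± 0.30) lower. The macrophage core had 2 of 18 higher, Lyz2 (2.08 ± 0.17) and Cd14 (1.97 ± 0.29) (2 higher and 1 lower adjusted over the list alone; median 0.01, adjusted p = 0.549). Neutrophil genes had 3 of 8 higher, such as S100a9 (2.90 ± 0.56) (5 adjusted over the list alone; median 3.02, adjusted p = 0.0667). Eosinophil genes had 1 of 6 lower, the lectin Siglecf (0 in both fiber libraries; 2 lower adjusted over the list alone; median -0.45, adjusted p = 0.187). Cell cycle genes had 1 of 15 lower, the mitotic kinase Plk1 (median -0.68, adjusted p = 0.161), and endothelial genes 2 of 8 (median 0.28 but mean -0.34, adjusted p = 0.363). Dendritic cell (1 of 8 higher, Cd209a; median 0.63, adjusted p = 0.238), B cell (1 of 9 higher, Ebf1; median 0.32, 0.817) and mural genes (1 of 8 higher; median 1.40, 0.179) had a single member each. For these 5 lists the counts were the same adjusted over the list alone. T cell genes had 0 of 8 (2 higher adjusted over the list alone; median 0.88, adjusted p = 0.357). NK cell (0 of 4; median -1.65, adjusted p = 0.92), adipocyte (0 of 10; median 0.57, 0.363) and cholesterol synthesis genes (0 of 14; median 0.18 but direction down, 0.996) had 0 adjusted over the list alone as well. Of the mast cell and basophil list 2 genes were tested, too few for a set test, and neither was called (1 higher adjusted over the list alone).

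In all, 873 genes were higher and 526 lower in SAM than in the other macrophages (1 and 4 of them listed at 0 in all libraries of the lower side), and 17 of 32 lists rose, 11 of them with an estimated correlation. Of the lower genes only 3 met the rule for naming: the death receptor Tnfrsf21 (-1.84 ± 0.22), the integrin gene Itgb2 (-1.28 ± 0.17) and Man2a2 (-1.24 ± 0.27). Man2a2 lost its call in 2 of 33 alternatives, and Tnfrsf21 and Itgb2 in 1 of 33 each. The raw gene-body table called 15 higher and 2 lower genes. Leaving out SAM fibers 2 gave 1082 and 2287, and leaving out vATM 1 or vATM 2 gave 518 and 527 higher genes. Voom with quality weights gave 806 higher and 79 lower. With RLE scaling, which moved the median log2 change of all genes from 0.02 to 0.19, 72.3% of the called genes were higher, against 62.4%. With log2(RPKM + 0.1) the share was 47.8% (median -0.12), and of the raw table it was 88.2% (median -0.30).

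The comparison of fibers with the fat around them asked what distinguishes macrophages on the nerve from their neighbors in subcutaneous fat. Fiber macrophages had more of the inflammatory and immediate-early transcripts. Of these, 14 of 19 pro-inflammatory genes were higher (16 adjusted over the list alone, median 3.001, adjusted p = 3.70e-21) and 12 of 18 immediate-early and heat-shock genes (16 adjusted over the list alone, median 1.85, adjusted p = 2.21e-22). Both had adjusted p = 0.0164 with an estimated correlation. Fibers had a hyaluronidase step that sATM did not have, so digestion and tissue cannot be told apart for either list. Ccl4 rose from 99.7 ± 26.8 CPM in sATM to 1246 ± 88.6 in fibers (3.64 ± 0.46, adjusted p = 9.49e-04), Egr1 from 123 ± 33.7 to 3613 ± 983 (4.87 ± 0.48). The receptor Tlr2 (3.001 ± 0.38), Cxcl1 (5.44 ± 0.86), Il1a (7.05 ± 1.16), Egr3 (6.13 ± 1.04), Maff (5.97 ± 1.60, adjusted p = 0.0443) and the cytokine Il10 (5.59 ± 1.25) rose too. In the other direction, some genes of resident adipose macrophages were lower in fibers. Retnla (chromosome 16, 48842552 to 48844461) fell from 2719.7 ± 2662 CPM in sATM to 98.4 ± 10.5 (-4.79 ± 0.94, adjusted p = 0.00939), Cd209f fell by 5.70 ± 1.05, and Ccl8 was lower as well (-3.23 ± 0.72). Stab1 was higher (2.38 ± 0.55), and the list did not pass (1 of 17 higher and 3 lower, and 4 and 4 adjusted over the list alone; adjusted p = 0.725). The lysozyme gene Lyz1 (-4.60 ± 0.96), the ferrireductase gene Steap3 (-4.18 ± 0.78), the ribonuclease genes Ear2 (-4.11 ± 0.64) and Ear12 (-3.98 ± 0.59), Aim1 (-4.71 ± 0.84) and Tmem154 (-4.50 ± 1.19) were lower too. With voom and quality weights these lower genes lost their calls: Retnla (adjusted p = 0.0602), Cd209f (0.141), Lyz1 (0.134), Steap3 (0.262), Ear2 (0.0917), Ear12 (0.0704), Aim1 (0.105) and Tmem154 (0.263). So did Il1a (0.188) and Maff (0.0774) among the higher ones.

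Other cell types' transcripts were again higher in fibers, whose DNA background (959 per M) was also above that of sATM (207). The neuron list rose (7 of 20, and 14 adjusted over the list alone; median 3.68, adjusted p = 2.00e-12). It includes Npy (3.95 ± 0.52), Uchl1 (3.62 ± 0.72) and Stmn2 (3.43 ± 0.69), and the neuronal gene Pcsk1n (7.24 ± 1.07) was among the largest increases. Camk2n1 was higher as well, with counts of 307 and 92 in fibers and 0 and 3 in sATM, too few there for a fold change. Schwann and satellite glia genes rose (6 of 16, and 8 adjusted over the list alone; median 3.93, adjusted p = 5.95e-07), as Apod (5.74 ± 1.05), Pmp22 (2.41 ± 0.49) and S100b (5.18 ± 1.20) show. The sATM levels of Pcsk1n and S100b lie under the floor of sATM 1 (0.764 CPM), so the sizes of their fold changes are uncertain. Fibroblast genes rose (4 of 12, and 5 adjusted over the list alone; median 2.64, 2.55 with genes absent on 1 side at their bound, adjusted p = 6.57e-04), among them Col1a2 (3.31 ± 0.69). Each of these had adjusted p = 0.0164 with an estimated correlation. The microglia list rose (9 of 17 higher, and 10 higher with 1 lower adjusted over the list alone; median 1.36, 1.53 at the bound, adjusted p = 3.44e-11, 0.00122 with an estimated correlation). Sparc (2.88 ± 0.36) and Siglech (3.42 ± 0.46) were among them. Erythroid genes rose with the preset correlation only (4 of 8, and 4 adjusted over the list alone; adjusted p = 7.92e-05, and 0.142 with an estimated correlation). So did central glia genes (2 of 9, and 3 adjusted over the list alone; adjusted p = 0.0017, and 0.118) and neurotrophic factors (1 of 12, Pdgfb at 1.52 ± 0.41, and 1 adjusted over the list alone; 0.0248, and 0.118). Maoa (2.74 ± 1.05, adjusted p = 0.15), Slc6a2 (3.29 ± 1.74, adjusted p = 0.277), Slc29a4 (adjusted p = 0.291), Slc22a3 (0.352), Slc18a2 (0.426), Aldh2 (0.945), Akr1a1 (0.287), Adgre1 (0.458) and Ptprc (-1.37 ± 0.40, adjusted p = 0.0625) were not called. Ptprc was lower without SAM fibers 2 (-1.89, adjusted p = 0.0154) or sATM 2 (-1.91, 0.0405), with DESeq2 (-1.12, 0.0312) and without the filter (-1.51, 0.0251). Maoa passed in 5 of 29 alternatives and Slc29a4 in 2 of 28. Those of Maoa include the fit without sATM 2, where the remaining sATM library is listed at 0 (raw count 34), so no fold change is given.

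In total 283 genes were higher and 457 lower in fibers than in sATM, of which 16 and 119 were listed at 0 in both libraries of the lower side. Among them, Cxcl2, Hsp90aa1 and Mxd1 were listed at 0 in sATM and Cd209g in fibers. Their raw gene-body counts in sATM were 407 and 3249 for Cxcl2, up to 6241 for Hsp90aa1 and 372 and 704 for Mxd1. For Cd209g they were 41 and 11 in fibers. The raw table called 0 genes and reversed Hsp90aa1 (-2.47) and Mxd1 (-0.50). With edgeR on only these 4 libraries 0 were called (3286 genes had an unadjusted p below 0.05 in the fit of all libraries, against 764 for chance; DESeq2 over all libraries called 1034 and 785). Without SAM fibers 2 there were 464 higher and 2515 lower genes, without sATM 1 97 and 275, and without sATM 2 96 and 170. Without SAM fibers 1 there were 218 lower genes, and without vATM 1 or vATM 2 161 and 160 higher and 250 lower. With RLE scaling, which moved the median log2 change of all genes from 0 to 0.28, 57.1% of the called genes were higher, against 38.2%. With DESeq2 the share was 56.8% and with log2(RPKM + 1) 63.8%, and the median was -0.63 for raw counts. Voom with quality weights turned the balance to 104 higher and 5 lower and ended the calls of Apod (0.0548), Camk2n1 (0.171), Hsp90aa1 (0.157) and Cd209g (0.135). Without sATM 2 the calls of Retnla (adjusted p = 0.0524), Lyz1 (0.131), Steap3 (0.0945), Apod (0.0873), Camk2n1 (0.0523), Hsp90aa1 (0.0554), Il10 (0.192), Maff (0.225) and Tmem154 (0.186) were lost. Without sATM 1 those of Apod (0.0737), Camk2n1 (0.0556), Il10 (0.124) and Tmem154 (0.0556) were lost. Il10 lost its call without SAM fibers 2 as well (0.0689), and Maff and Tmem154 lost theirs in 15 of 29 alternatives each.

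Ganglia and fibers, the SAM sources, differed from each other most clearly in microglial genes. Of that list 11 of 17 genes were higher in ganglia (15 adjusted over the list alone, median 1.80, adjusted p = 3.30e-19, 2.61e-04 with an estimated correlation). The purinergic receptor gene P2ry12 (chromosome 3, 59216271 to 59262831) averaged 205 ± 11.97 CPM in ganglia against 24.3 ± 2.70 in fibers (3.08 ± 0.36, adjusted p = 4.17e-04). Crybb1 had 135, 195 and 135 counts in ganglia and 0 and 2 in fibers, too few there for a fold change. Tmem119 (4.39 ± 0.55) and Olfml3 (4.27 ± 0.63) followed, as did Pmepa1 (3.80 ± 0.61), Ctc1 (4.57 ± 0.66), Lrch3 (3.60 ± 0.79), Ulk2 (3.45 ± 0.77) and F11r (3.16 ± 0.53). The iron exporter Slc40a1 was also higher (2.44 ± 0.34). Single inflammatory and immediate-early genes were lower in ganglia, though both lists lost their calls with an estimated correlation (adjusted p = 0.0873 and 0.0531). Egr1 averaged 3613 ± 983 CPM in fibers and 352 ± 85.7 in ganglia (-3.36 ± 0.38, adjusted p = 2.92e-04). Ier2 (-2.79 ± 0.31), Nfkbiz (-2.75 ± 0.41), Cxcl2 (-6.72 ± 1.09), the protease gene Mmp9 (-6.47 ± 0.84), the demethylase gene Kdm6b (-5.89 ± 1.05), Maff (-5.78 ± 1.31), Noct (-4.996 ± 0.91) and the lectin Clec4e (-4.99 ± 0.80) were lower in ganglia. So was Areg, with 0, 3 and 0 counts in ganglia and 12 and 278 in fibers. Cxcl2 had corrected counts of 6, 69 and 0 in ganglia, where its raw counts were 1311, 1235 and 1023. The size of its change is therefore uncertain. On raw gene-body counts the changes were smaller, -2.08 for Cxcl2, -2.98 for Mmp9 and -1.82 for Kdm6b. They were -1.12 for Maff, -1.38 for Noct and -2.32 for Clec4e. The monocyte genes Ly6c2 (20.96 ± 15.9 CPM against 204 ± 119.7, -3.28 ± 0.66) and Plac8 (-3.07 ± 0.65) were lower too, though their list lost its call as well (adjusted p = 0.21).

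With the preset correlation 11 lists fell and 3 rose in ganglia, and only the microglia list passed with an estimated one. The pro-inflammatory list had 12 of 19 lower (15 adjusted over the list alone; median -2.05, adjusted p = 5.82e-13, and 0.0873 with an estimated correlation). The immediate-early list had 10 of 18 (13 adjusted over the list alone; median -1.42, adjusted p = 9.38e-16, and 0.0531). Monocyte genes had 4 of 10 lower (6 adjusted over the list alone; adjusted p = 2.87e-05, and 0.21). Neuron genes had 2 of 20 lower, among them Npy at -2.33 ± 0.42 (5 adjusted over the list alone; adjusted p = 8.47e-06, and 0.104). Schwann genes had 1 of 16 (1 adjusted over the list alone; adjusted p = 0.00102, and 0.104), and fibroblast genes 2 of 12 (3 adjusted over the list alone; 0.0021, and 0.0531). Erythroid genes had 3 of 8 lower (3 adjusted over the list alone; adjusted p = 0.00776, and 0.283) and anti-inflammatory genes 3 of 16 (4 adjusted over the list alone; 0.00807, and 0.227). Neutrophil genes had 1 of 8 lower, Mmp9 (1 adjusted over the list alone; adjusted p = 0.00254, and 0.227). T cell (0 of 8; adjusted p = 0.0139, and 0.254) and central glia genes (0 of 9; 0.0475, and 0.326) had 0 adjusted over the list alone as well. The macrophage core rose with 2 of 18 higher, the protease Ctss and the receptor Fcgr1 (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0187, and 0.254). Interferon genes rose with 1 of 15 (1 adjusted over the list alone; adjusted p = 0.0128, and 0.383). DNA background was lower in ganglia (351 per M) than in fibers (959). Slc6a2 (-1.24 ± 1.41, adjusted p = 0.605), Maoa (-0.23 ± 0.88, adjusted p = 0.89), Slc18a2 (adjusted p = 0.3), Slc22a3 (0.705), Slc29a4 (0.366), Aldh2 (0.718), Akr1a1 (0.246), Adgre1 (0.109) and Ptprc (0.939) did not differ by the test. Slc18a2 passed without SAM fibers 2 (adjusted p = 0.0354), but the remaining fiber library is listed at 0 (raw count 776), so no fold change is given.

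In total 435 genes were higher and 194 lower in ganglia than in fibers. Of these, 125 of the higher ones were listed at 0 in both fiber libraries and 8 of the lower ones in all ganglia libraries. Ptprj was listed at 0 in fibers with raw gene-body counts of 4595 and 7340. Hsp90aa1, Il10 and Mxd1 were listed at 0 in ganglia, with raw counts of 6033, 9307 and 3407, of 95, 182 and 191, and of 1015, 1522 and 903. The raw table called 0 genes and turned Hsp90aa1 (3.36) and Mxd1 (1.63). The count in edgeR with an unadjusted p below 0.05 was 3049, and DESeq2 called 805 higher and 632 lower. On only these 5 libraries edgeR called 8 higher and 24 lower. Higher genes numbered 2469 without SAM fibers 2, 221 without SAM fibers 1, 235 without SAM ganglia 2, 253 without vATM 1 and 257 without vATM 2. Lower genes numbered 111 without SAM ganglia 2, 123 without SAM ganglia 1 and 117 without vATM 1 or vATM 2. With RLE scaling, which moved the median log2 change of all genes from 0 to -0.25, 50.3% of the called genes were higher, against 69.2%. With DESeq2 the share was 56.02% and with log2(RPKM + 1) 40.4%, and the median was 0.53 for raw counts. Voom with quality weights turned the balance to 13 higher and 101 lower. It ended the calls of Ctc1 (adjusted p = 0.148), Lrch3 (0.306), Ulk2 (0.201), F11r (0.0727), Ptprj (0.393), Kdm6b (0.0817), Maff (0.0588) and Hsp90aa1 (0.0607). The fit of only these groups ended those of Ctc1 (0.139), Lrch3 (0.3), Ulk2 (0.31), F11r (0.108), Kdm6b (0.0949), Maff (0.0851), Cxcl2 (0.0706), Areg (0.101), Noct (0.162) and Clec4e (0.0704). Without SAM fibers 2 Areg (adjusted p = 0.162) and Maff (0.156) lost their calls, and Maff also without SAM ganglia 1 (0.0613), SAM ganglia 2 (0.0537) or SAM ganglia 3 (0.0596).

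Ganglia and microglia, macrophages of peripheral and central nervous tissue, were compared directly. Ganglion macrophages had far more of the immediate-early genes, 18 of 18 being higher (18 adjusted over the list alone, median 5.42). Fosb stood at 171 ± 21.9 against 0.210 ± 0.230 CPM (9.42 ± 0.57, adjusted p = 1.48e-07), followed by Fos (7.82 ± 0.71), Dusp1 (7.72 ± 0.50), Atf3 (6.27 ± 0.32) and Hspa1a (7.12 ± 0.40). They also had more of the resident adipose and perivascular genes (15 of 17, and 15 adjusted over the list alone; median 4.58). Examples are Cbr2 (271 ± 45.4 against 1.77 ± 2.30 CPM, 7.01 ± 0.63), Cd163 (6.26 ± 0.56), F13a1 (5.78 ± 0.55) and Retnla (7.88 ± 1.04). MHC class II genes were higher too (7 of 10, and 7 adjusted over the list alone; median 4.01), as the class II regulator Ciita (5.41 ± 0.40) and Cd74 (6601 ± 1256 against 62.2 ± 49.01 CPM, 6.72 ± 0.63) show. Microglia had more of their own markers, 14 of 17 being lower in ganglia and Ccl12 higher (15 lower and 1 higher adjusted over the list alone, median -2.45). Lower were P2ry12 at 205 ± 11.97 against 3932 ± 696 CPM (-4.26 ± 0.32), the fructose transporter gene Slc2a5 (-5.84 ± 0.35) and Sparc (-4.53 ± 0.31). Further genes lower in ganglia were Slco4a1 (-6.52 ± 0.96), Csmd3 (-6.48 ± 1.35), the transcription factor Sall3 (-6.31 ± 1.06), Ecscr (-6.19 ± 0.72), Serpine2 (-6.18 ± 0.55), the adenosine receptor Adora3 (-5.82 ± 0.82), Lag3 (-5.59 ± 0.75) and Mlph (-5.44 ± 1.03). Upk1b was listed at 0 there (raw counts 2, 19 and 206). Further genes higher in ganglia were Il1b (7.37 ± 0.56), Ccl7 (7.72 ± 0.93), the interferon-induced Ifi27l2a (7.81 ± 0.89) and Cmah (7.42 ± 1.32). The microglial levels of Fosb, Retnla, Ccl7, Ifi27l2a and Cmah lie under the floor of Microglia 2 (0.842 CPM), and the ganglion level of Slco4a1 under that of SAM ganglia 1 (0.693 CPM), so the sizes of these fold changes are uncertain.

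Of 32 lists 17 rose and 2 fell in ganglia against microglia, 12 of them also with an estimated correlation. The 4 lists above passed both ways (adjusted p = 2.27e-110, 4.50e-35, 1.41e-18 and 1.54e-36; 5.14e-05, 6.10e-04, 0.00333 and 2.09e-05 with an estimated correlation). Pro-inflammatory genes had 12 of 19 higher and 1 lower (13 and 2 adjusted over the list alone; adjusted p = 6.71e-19 and, with an estimated correlation, 0.0109). In the same order of values, anti-inflammatory genes had 7 of 16 higher (9 adjusted over the list alone; 6.28e-14 and 0.00327). Interferon genes had 11 of 15 higher, such as the antiviral Rsad2 at 3.57 ± 0.44 (11 adjusted over the list alone; 8.03e-16 and 0.0118). Red pulp genes had 8 of 15 higher, such as the heme oxygenase Hmox1 at 3.52 ± 0.40, and 1 lower (9 and 1 adjusted over the list alone; 8.62e-11 and 5.70e-04). Lipid handling genes had 5 of 14 higher and 3 lower (7 and 3 adjusted over the list alone; 5.63e-05 and 0.0453), Apoe standing at 27011 ± 8748 against 689.9 ± 218 CPM (5.29 ± 0.38). Catecholamine synthesis had 2 of 8 higher, Gch1 at 2.52 ± 0.47 and Cyb561, whose microglial level is under the floor (3 adjusted over the list alone; 0.00614 and 0.0393). Fibroblast genes had 3 of 12 higher (5 adjusted over the list alone; 0.00144 and 0.021) and dendritic cell genes 2 of 8 (2 adjusted over the list alone; 8.64e-05 and 0.0221). The next 6 lists lost their calls with an estimated correlation. Neuron genes had 4 of 20 higher, Npy at 2.55 ± 0.41 among them, and 1 lower (9 and 1 adjusted over the list alone; median 2.32; 4.83e-06 and 0.0521). Monocyte genes had 5 of 10 higher (7 higher and 1 lower adjusted over the list alone; 1.91e-06 and 0.0508) and erythroid genes 4 of 8 (5 and 1 adjusted over the list alone; 6.25e-04 and 0.131). Complement genes had 7 of 19 higher and 2 lower (8 and 2 adjusted over the list alone; 6.25e-04 and 0.112) and cholesterol synthesis 3 of 14 higher (4 adjusted over the list alone; 0.0204 and 0.247). Eosinophil genes fell, with Siglecf lower and under the floor in ganglia (1 of 6, and 1 adjusted over the list alone; 0.0373 and 0.0873).

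Norepinephrine genes rose between ganglia and microglia with the preset correlation only (2 of 8, and 2 adjusted over the list alone; median 1.02, adjusted p = 0.0373, and 0.0873 with an estimated correlation). The called genes were Aldh2 (24.97 ± 14.2 against 3.70 ± 1.61 CPM, 2.72 ± 0.52, adjusted p = 0.003) and Maoa (3.15 ± 0.89, adjusted p = 0.0411). The Aldh2 call was lost in 2 of 29 alternatives. The Maoa call was lost in 11 of 29 alternatives, as without Microglia 1 (0.155), Microglia 2 (0.101), Microglia 3 (0.147), SAM ganglia 1 (0.0906), SAM ganglia 2 (0.154), SpM 1 (0.054), vATM 1 (0.0699) or vATM 2 (0.0716), with log2(RPKM + 0.1) (0.118) and in the raw table (0.589). Slc6a2 (2.69 ± 1.38, adjusted p = 0.353), Slc22a3 (adjusted p = 0.899), Slc29a4 (0.885), Slc18a2 (0.944) and Ptprc (0.318) were not called. Akr1a1 (0.84 ± 0.24, 0.041) and Adgre1 (0.97 ± 0.25, 0.0235) passed the test but not the minimum fold change. Adgre1 reached it without SAM ganglia 1 (1.08) or SAM ganglia 3 (1.02), with voom (1.04) and in the fit of only these groups (1.01). In total 750 genes were higher and 310 lower, 26 and 7 of them listed at 0 in all libraries of the lower side. The raw table called 58 higher and 4 lower genes and voom 707 lower genes. Lower genes numbered 178 without Microglia 1, 192 without Microglia 3 and 489 without SAM fibers 2. With log2(RPKM + 1) 40.1% of the called genes were higher (median log2 change of all genes -0.26) and with log2(RPKM + 0.1) 51.9% (median -0.46), against 70.8% (median -0.13). Of the raw table it was 93.5%.

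Subcutaneous and visceral fat macrophages served as a comparison of adipose depots. The subcutaneous cells had more of the genes of circulating monocytes. Plac8 (chromosome 5, 100553733 to 100572205) averaged 173 ± 173 CPM in sATM and 1.69 ± 0.998 in vATM (6.66 ± 0.91, adjusted p = 0.016) and Ly6c2 170.3 ± 157 and 2.67 ± 0.294 (5.98 ± 0.89, adjusted p = 0.0227). The G protein subunit gene Gngt2 rose as well (4.42 ± 0.64). The visceral cells had more Slc40a1 (chromosome 1, 45908070 to 45925594; 61.5 ± 14.3 against 9.87 ± 2.79 CPM, -2.62 ± 0.35, adjusted p = 0.016), Slco2b1 (-1.84 ± 0.30, adjusted p = 0.0438) and Pxdc1 (its sATM level is under the floor of sATM 1, and it was named after its value was seen). The monocyte list was higher in sATM (2 of 10, and 7 adjusted over the list alone; median 4.24, adjusted p = 2.36e-18). So were interferon (0 of 15, and 3 adjusted over the list alone; median 1.32, 2.79e-15; Rsad2 at 2.28 ± 0.50 and adjusted p = 0.145) and neuron genes (0 of 20, and 4 adjusted over the list alone; median 2.61, 2.17 at the bound, 5.96e-16). Erythroid genes were higher (0 of 8, and 5 adjusted over the list alone; median 2.44, 6.41e-10). Resident adipose and perivascular genes were lower in sATM (0 of 17, and 8 adjusted over the list alone; median -1.54, 3.75e-18; Gas6 at -1.89 ± 0.43 and adjusted p = 0.167). So were microglia-list genes (0 of 17, and 4 adjusted over the list alone; median -0.39, 1.23e-04). These 6 lists passed with an estimated correlation (adjusted p = 0.0157, 0.0175, 0.0157, 0.0303, 0.0157 and 0.0157). Central glia (0 of 9; adjusted p = 0.0158), neutrophil (0 of 8, and 1 adjusted over the list alone; 1.39e-04) and red pulp genes (1 of 15 lower, and 3 lower with 1 higher adjusted over the list alone; 0.0398) lost their calls with an estimated correlation (adjusted p = 0.27, 0.107 and 0.107).

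Only 3 genes were higher and 3 lower in sATM than in vATM, and 569 of 15289 had an unadjusted p below 0.05, fewer than the 764 expected by chance. The tested norepinephrine genes (Maoa -1.63 ± 1.01, Slc6a2 with 11 and 0 counts in sATM and 2 and 2 in vATM), Adgre1 and Ptprc were not called (adjusted p = 1, 1, 1 and 1). The raw table and edgeR on only these 4 libraries called 0 genes, and DESeq2 called 79 higher and 32 lower (71.2% higher, against 50%). With limma on log2(RPKM + 0.1) there were 5 and 0, with a median log2 change of all genes of 0.16 against -0.04. Without sATM 2 there were 52 higher and 16 lower. Without sATM 1, vATM 1 or vATM 2 no gene was called, with 1 library left in a group. Fold changes stayed large in these fits, from 5.04 to 7.32 for Plac8, 4.59 to 5.99 for Ly6c2 and -2.20 to -2.88 for Slc40a1. Plac8 (adjusted p = 0.0723, 0.28 and 0.317), Ly6c2 (0.0723, 0.492 and 0.317), Gngt2 (0.0723, 0.492 and 0.317), Slc40a1 (0.688, 0.25 and 0.576) and Slco2b1 (1, 0.622 and 1) all lost their calls. Ly6c2 (0.0653) and Gngt2 (0.0629) also lost theirs without SAM ganglia 2, Slc40a1 (0.0656) without Microglia 1, and Slco2b1 in 13 of the 15 single-library fits.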

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

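The tests given here were chosen after the results were seen, apart from the regrouping of libraries at random. Of the 1399 genes called between SAM and the other macrophages, 342 also differed between ganglia and fibers, 227 of them higher in ganglia and 115 higher in fibers. For unrelated lists 57.6 would be shared, but both comparisons use the same libraries. The averaged SAM value of genes such as Fosb or Olfml3 therefore describes neither source by itself. Olfactory receptor genes, 1125 in number and silent in most macrophages, had raw gene-body counts above the floor in all 15 libraries, from 32.9 to 1233 per M raw counts.

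Slc6a2 and Maoa were higher in SAM libraries. With DNA background as a covariate Slc6a2 stood at 3.88 ± 0.92 (adjusted p = 0.0161) and Maoa at 3.35 ± 0.59 (adjusted p = 0.00294). The covariate's slope rests on differences within groups. As background rose, corrected Slc6a2 counts fell in ganglia (49, 25 and 10) but rose in spleen (1, 7 and 11). A slope shared by all groups cannot follow both. The fit therefore argues only against a shared trend, and DNA background is not excluded for either gene. Slc6a2 per count of Th and Dbh was 84 to 318 in ganglia, 95 to 622 in fibers and 56 to 171 in the other groups, a log2 ratio of -0.78 for SAM over the rest (95% interval -1.50 to 0.03 over 2000 resamples). Spleen, with 19 counts to 5, drives most of that difference, and without it the rest had 37 to 166, a log2 ratio of -0.23 (95% interval -0.83 to 0.81). Neither interval shows more Slc6a2 for its neuronal RNA in SAM, but counts are small, and reads carried over between libraries would give the same. Neuronal RNA is therefore not excluded as the source of Slc6a2 and not shown to be it. That test and its bounds were written after its counts had been looked at and replaced one that could not decide (-1.24 ± 1.41 between ganglia and fibers, against a neuron-list median of -1.84). For Maoa the change between ganglia and fibers lay 1.82 standard errors from the neuron-list median. Its counts against those of Th and Dbh were 258 to 318 in ganglia, 133 to 622 in fibers and 206 to 171 in the other groups. Of the latter, vATM held 129 to 17, which shows Maoa RNA without much neuronal RNA. Maoa thus did not keep a fixed ratio to Th and Dbh, but this ratio was not tested. Neuronal and macrophage sources cannot be told apart in SAM.

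Immediate-early and heat-shock genes were higher in SAM libraries. Collagenase time is argued against as the only cause, since fat was far above brain and spleen after the same 30 minutes (median 4.93, 18 of 18 higher, p = 1.01e-05 with an estimated correlation), and all 18 genes still passed with the DNA covariate. The hyaluronidase step of the fibers (median 1.85 against sATM) and the trypsin step of the ganglia (median 0.69 against both fat groups, 3 of 18 higher, p = 0.0386 with an estimated correlation) cannot be told apart from tissue, since each was used on 1 tissue only. The trypsin test was added after a joint test of both enzymes could not decide. Digestion was not tested for the pro-inflammatory list. Both SAM sources had a second enzyme step that the other tissues did not have, so for that list digestion and tissue cannot be told apart either.

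Genes lower in fibers than in sATM were often listed at 0 in fibers. Their genomic span was 1.53 times that of genes higher in fibers (95% interval 1.21 to 1.99; 18.6 against 12.2 kb), but all lower genes spanned 20.9 kb, so the span does not set the genes listed at 0 apart from other lower genes. On raw gene-body counts the genes listed at 0 were not lower in fibers than in sATM, relative to all genes. Their median log2 change from sATM to fibers, minus that of all genes, was 0.10, against -0.95 for all lower genes. The ratio is only just past the bound of 1.5, and all tested genes spanned 16.9 kb. Too much may have been removed as DNA, or these genes may be lower in the cells, and both stay open.

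Regrouping the 15 libraries at random gave at most 76 called genes in 99 other groupings for SAM against the others, where the real groups gave 1399, so 1 of 100 reached the real count. A first run of 50 had a highest of 45. Each regrouping mixed tissues within its groups, which raises the spread and leaves few genes to call. The test therefore shows only that the tissues differ, and it cannot show a difference particular to SAM. For ganglia against microglia the real groups gave 1060 and no other grouping any, but 10 splits are too few to judge.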

How the results depend on the processing

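Settings named as added were chosen after the results were seen, the others beforehand. Other settings moved 76 of 217 counts and medians of the comparisons, and leaving out single libraries moved 49 of 240. For named genes 1682 of 1868 results stayed the same, 171 were weaker, 11 stronger and 4 reversed. Over single libraries left out 1822 of 1915 stayed, with 87 weaker and 6 stronger. These results include genes not called in the main fit, such as most norepinephrine genes. A gene called in neither fit was counted as the same, whatever its sign. The shares therefore overstate how steady the calls themselves were. Counts below are higher then lower genes. The raw gene-body table gave 15 and 2 for SAM against the other macrophages, 0 and 0 for fibers against sATM, 0 and 0 for ganglia against fibers, 58 and 4 for ganglia against microglia and 0 and 0 for sATM against vATM, with 0 norepinephrine genes, 16 lists for fibers against sATM and 14 for the fat groups. It reversed Hsp90aa1 (-2.47) and Mxd1 (-0.50) in fibers against sATM and Hsp90aa1 (3.36) and Mxd1 (1.63) in ganglia against fibers, all genes listed at 0 on 1 side of the corrected table. DESeq2 gave 1398 higher genes in SAM, 1034 and 785 in fibers, 805 and 632 in ganglia against fibers, 532 lower in ganglia against microglia, and 79 and 32 between the fat groups. RLE factors gave 281 lower genes in fibers. Without the filter there were 825 lower genes in SAM, 689 lower in fibers, and 67 and 15 between the fat groups. With log2(RPKM + 1) there were 815 higher in fibers, 617 lower in ganglia against fibers, 814 lower in ganglia against microglia, 0 lower in sATM and 1 norepinephrine gene, and with no filter besides 567 higher in SAM, 708 higher in fibers, 572 lower in ganglia against fibers, 454 and 630 in ganglia against microglia, 0 lower in sATM and 1 norepinephrine gene. With log2(RPKM + 0.1) there were 498 lower in ganglia against microglia, and 5 and 0 between the fat groups. Voom with quality weights gave 79 lower in SAM, 104 and 5 in fibers, 13 and 101 in ganglia against fibers, 707 lower in ganglia against microglia, and 21 and 14 between the fat groups. Fits of only the groups compared gave 0 and 0 in fibers, 8 and 24 in ganglia against fibers, 478 lower in ganglia against microglia, and 0 and 0 between the fat groups. With an estimated correlation 11 lists passed for SAM, 1 for ganglia against fibers and 12 for ganglia against microglia. Without spleen in the reference 517 genes were higher in SAM. Among alternatives added after the data were seen, DNA background as a covariate gave 1 and 1 between the fat groups, leaving out the library with most background in each group gave 303 lower in fibers and 56 and 43 between the fat groups, and genes called in both count tables numbered 15 and 1, 0 and 0, 0 and 0, 52 and 4, and 0 and 0 in the order of comparisons above. The cause of these shifts was not tested.

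With the replicate block the counts were 821 and 499 for SAM, 258 and 407 for fibers, 397 and 155 for ganglia against fibers, 735 and 312 for ganglia against microglia, and 10 and 3 between the fat groups. Of 33 same-number correlations of residuals 17 were at or below 0.1, and 8 of 15 libraries were closest to one of their own number. The median was 0.0951 for the same number, against -0.0689 for other numbers. Replicate 1 had a larger Rn45s share, a smaller Lars2 share and fewer detected genes than replicate 2 in all 6 groups. Its DNA background was lower than that of replicate 2 in every group other than fibers. The labels do not explain these differences. Replicate numbers were thus not shown to pair libraries across tissues. In these measures, though, libraries did differ by number, as a batch would make them. The main fit does not include a batch. Under the block, calls ended for Slc22a3 in SAM (adjusted p = 0.0505), Maff (0.0865) and Tmem154 (0.0649) in fibers, Areg (0.0608) and Maff (0.0511) in ganglia against fibers, and Maoa in ganglia against microglia (0.0629).

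Leaving out each library in turn gave ranges of 518 to 1082 and 370 to 2287 for SAM, 96 to 464 and 170 to 2515 for fibers, 221 to 2469 and 111 to 268 for ganglia against fibers, 559 to 906 and 178 to 489 for ganglia against microglia, 0 to 52 and 0 to 16 between the fat groups, and 1 to 3 norepinephrine genes (1 without SAM fibers 1, vATM 1 or vATM 2). Lists passing ranged over 16 to 20, 9 to 13, 10 to 15, 17 to 19 and 7 to 14 (14 without sATM 2). Counts moved more than 1.5-fold in SAM without vATM 1, vATM 2 or SAM fibers 2, in fibers without either fiber, sATM or vATM library, in ganglia against fibers without SAM fibers 1, SAM fibers 2, SAM ganglia 1, SAM ganglia 2, vATM 1 or vATM 2, and in ganglia against microglia without Microglia 1, Microglia 3 or SAM fibers 2. Between the fat groups they moved without any library other than Microglia 2, SpM 2 or SpM 3.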

Other observations

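Tests named in this part were chosen after the results were seen, and levels are given without a test unless a p is printed. The share of the microglial level found in ganglion macrophages differed from gene to gene. Cx3cr1, the fractalkine receptor, averaged 1803 ± 331 CPM in ganglia and 4627 ± 487 in microglia, Olfml3 393 ± 100.5 and 1923 ± 416, Siglech 232 ± 77.3 and 1125 ± 279, Tmem119 150.4 ± 31.6 and 1351 ± 268, P2ry12 205 ± 11.97 and 3932 ± 696, and the transcription factor Sall1 12.8 ± 2.21 and 404 ± 22.5. Fibers held 340.3 ± 78.4 CPM of Cx3cr1 and 7.28 ± 3.23 of Tmem119, and Sall1 was listed at 0 in both fiber libraries. Apoe was highest in ganglia, 27011 ± 8748 CPM against 10628 ± 795 in fibers and 689.9 ± 218 in microglia.

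Single genes of recruited cells and of antigen presentation had different orders of level among the tissues. Ccr2, the receptor that brings monocytes into tissue, averaged 1029 ± 2.68 CPM in sATM, 824 ± 193 in vATM, 601 ± 189 in ganglia and 267 ± 97.2 in fibers, but 18.6 ± 19.7 in microglia and 3.93 ± 3.83 in spleen. Ly6c2 had another order, 204 ± 119.7 in fibers, 170.3 ± 157 in sATM, 20.96 ± 15.9 in ganglia and 2.67 ± 0.294 in vATM. Cd74 lay between 6256 and 7832 CPM in the ganglion, fiber and fat groups, with 1993 in spleen and 62.2 in microglia. The vessel-associated receptor Lyve1 was highest in vATM (241 ± 52.9 CPM, against 51.7 ± 37.8 in sATM), and the chemokine receptor Ccr3 averaged 803 ± 135 CPM in spleen and at most 4.04 elsewhere.

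One hypothesis is that ganglion macrophages hold more of a microglia-like program than fiber macrophages do. The microglia list was higher in ganglia than in fibers with the preset and the estimated correlation (adjusted p = 3.30e-19 and 2.61e-04). With the preset correlation alone, the only one run for these settings, it stayed higher in the raw gene-body counts (adjusted p = 1.09e-13), with the DNA covariate (6.92e-21) and without the library with most background in each group (2.95e-13). Whether digestion alters this list was not tested, and sorting both sources with the same enzymes would be needed. A second hypothesis is that SAM may take up norepinephrine by Slc6a2. The present counts exclude neither neuronal RNA in the sorted cells nor DNA background. Relative to Th and Dbh the log2 ratio was -0.78, and -0.23 without spleen, in a test written after its counts had been seen. Reads over Slc6a2 exons in single cells that lack Th and Dbh, or staining of the protein on F4/80-positive cells, would be needed.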
